A study of Mus musculus with 16 samples.

How the data were processed

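Gene expression was measured on 16 arrays printed with 15488 spots of mouse cDNA clones, each hybridised with a Cy3-labelled and a Cy5-labelled RNA. The labels place 4 arrays in each of 4 comparisons of an asymmetrically self-renewing culture with a symmetrically self-renewing one. Per the design text, total RNA came from 2 independent isolations per comparison and each RNA was labelled with both dyes. No label says which arrays share an RNA, so each array entered the fit on its own and p-values measure the spread between arrays.

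Per the file headers, the scanner files hold the mean intensity and the median local background intensity of each spot in each dye, in 2 exposures, with no background subtracted. A signal-to-noise score and the percent of saturated pixels of each spot are also given, per the file headers. The scanner software's own log2 ratio per spot was deposited in the same files. The authors' deposited value table holds 1 log10 ratio per clone and array for 13859 clones. Its slope on the scanner's log2 ratio was between 0.297 and 0.310 in size, against 0.301 for log10 of 2, and its column medians lay between −0.0492 and 0.0628. Its sign followed Cy3 over Cy5 on odd-numbered arrays and Cy5 over Cy3 on even-numbered ones, and what centring the authors applied is not given in the sources used here. The table matched both exposures nearly equally, so the exposure behind it stays unknown.

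The orientation of the ratios was decided as follows. The labels give the asymmetric RNA in Cy3 on all arrays. The rule written in advance said that if arrays of a comparison correlated under −0.3 under the labels, each array would take the sign of the deposited table, provided that the arrays of a comparison then ran the same way, and that otherwise no direction would be given. Arrays 9 and 10 correlated at −0.388, and the table's signs were used for all arrays. Under the labels only comparison 3 fell under −0.3, and the arrays of comparison 1 correlated at 0.0578 to 0.757. Read for each comparison on its own, the rule would keep the labels in comparison 1. Read for all arrays together, it gives comparison 1 no direction, as under the table's signs its arrays of opposite dye order correlated at a mean of −0.199. The direction there is reported as likely, a departure from the rule, and was taken from the table, the header dye marks and the described labelling with both dyes. Over all clones the array values do not support it, as the average of arrays 1 and 3 correlated with that of arrays 2 and 4 at −0.251. Arrays of the same dye order correlated at 0.699 and 0.757. Gene-specific dye bias could give both patterns, so these correlations cannot decide the direction. Some list means go with it. That of p53 targets was 0.239, 0.338, 0.0820 and 0.192 on arrays 1 to 4, though the median of the list was −0.0648 on array 3. The means of the replication, mitosis and histone lists were below 0 on each array. Others changed sign between arrays, as ribosomal proteins did (0.144, 0.0294, −0.0110 and −0.146). In comparison 4 arrays of opposite dye order correlated at −0.202 to 0.261 under the table's signs. Not all of them ran the same way, so read for all arrays together the rule gives comparison 4 no direction either. Its direction rests mostly on the deposited signs and is a departure too. In comparison 2 the average of arrays 5 and 6 correlated with that of arrays 7 and 8 at −0.350 and no direction is reported. Every result was also computed under the labels' orientation and with comparison 2 turned, and the counts that moved by over 1.5 times and the results that reversed are given in the closing section.

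Background was corrected with normexp at an offset of 50 on the second exposure, and log ratios were normalised within each array by loess, in limma 3.58.1 under R 4.3.3. Of the spots, 241 were controls, empty or unnamed, and 1385 of the 15247 clones carried the array maker's flag and were left out, which left 13862. A clone was kept if its signal-to-noise score was at least 2 in either channel on at least 4 arrays, as 13850 were. Clones were named from the descriptions in the files and the gene name table given, which provided 1 symbol for 3757 clones (981 of them through a description of another species, and 4 by hand) and none for 11490. A gene with several clones, as 609 had, was represented by the brightest one, and 12966 genes and unnamed clones were tested, 2547 of them named. Cdkn1a and Cxcr6 were not measured by a named clone.

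The 16 arrays were fitted together with lmFit and eBayes, with 1 coefficient per comparison, 12 residual and 7.19 prior degrees of freedom, and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Each gene thus had 1 spread for all comparisons, so a wide spread in one comparison also weakened its calls in the others. The mean of the 4 coefficients and the mean of the first 3 minus the fourth were tested as contrasts. Of 21 gene lists, 18 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 over 5 contrasts, 90 tests in all, and again with an estimated correlation. The lists were p53 targets, zinc and metal response, purine and guanine synthesis, DNA replication, mitosis, histones and HMG proteins, ribosomal proteins, ribosome biogenesis, respiratory chain, proteasome, glycolysis and hypoxia, cholesterol synthesis, heat shock, matrix and mesenchymal genes, actin and contractile genes, epithelial, hematopoietic and stem cell markers, interferon response, adipocyte and muscle markers, and the study's candidates. The genes named are, per comparison, the 10 largest called rises and falls among named genes whose arrays all ran one way, for the mean the 10 highest and 10 lowest by the smallest, in size, of the 4 ratios among named genes called in the mean with one sign in all 4, a few genes fixed in advance (among them Trp53, Mdm2, Ccng1, the metallothioneins and H2az1), and up to 4 members per list. The 12 genes drawn in the gene figure were chosen after the results were seen. A few genes are not reported here by name and stay in the fit, the lists and the counts.

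Tested on simulated changes of 0.5 log2 in 100 genes and of 1 log2 in 100 others, the fit recovered 74% of the smaller ones in comparison 1, 73% in comparison 2, 69% in comparison 3 and 72% in comparison 4. Over both sizes 3.89%, 3.37%, 6.63% and 3.91% of calls were false, against 7.41% in the mean of the 4 comparisons, and there was no call when nothing was changed. The simulated noise was drawn independently for each array, without shared RNA or a dye effect, so these rates need not hold for the real arrays. The groups, the test, the lists, the naming rule and most alternatives were fixed before the data were examined. The second exposure, the score minimum, the reading of the orientation, the names given by hand and the refits that turn or leave out arrays of comparison 2 were chosen afterwards. Alternatives covered the background correction, normalization, filter, flags, probe choice, exposure, dye effect, array weights, pairing of arrays, orientation, minimum change, separate fits and leaving out each array. No slide or scan batch was found in the files used here, so none was fitted. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.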

Results

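Messenger RNA was measured in cultured mouse cells on 16 printed arrays of cDNA clones. Each array carried a pair of dye-labelled RNAs, one from cells described as self-renewing asymmetrically and one from a matched culture described as self-renewing symmetrically. In asymmetric self-renewal a dividing cell gives 1 daughter that keeps dividing and 1 that stops, whereas in symmetric self-renewal both daughters keep dividing. The design asked which genes change in the same way in 4 such comparisons, each on 4 arrays. Comparison 1 set mouse embryo fibroblasts with a zinc-inducible p53 transgene against fibroblasts lacking p53, both in 65 micromolar zinc. Comparison 2 set the p53-inducible fibroblasts in zinc against the same line without zinc. Comparison 3 set mouse mammary epithelial cells (MMECs) whose p53 transgene is induced at low temperature against cells with an empty vector. Comparison 4 set p53-inducible fibroblasts carrying an empty vector against fibroblasts carrying a transgene for type II inosine monophosphate dehydrogenase (IMPDH), the rate-limiting enzyme of guanine nucleotide synthesis. In comparison 4 both cultures were in zinc and expressed p53, so it was the comparison without a difference in p53.

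The median spot signal was 2219 to 3581 intensity units in Cy3 in comparison 1, 1581 to 1879 in comparison 2, 234 to 329 in comparison 3 and 669 to 839 in comparison 4. Between 73.9% and 96.2% of clones were above background in both dyes on an array. All values below are log2 ratios of the asymmetric over the symmetric culture, given as mean ± SD over arrays. The labels put the asymmetric RNA in Cy3 on every array, but the authors' deposited values take the opposite sign on the even-numbered arrays, and the directions given here follow the deposited values. Under these signs, arrays of comparison 3 with opposite dye orders correlated at r = 0.0890 to 0.388 over all clones, which are not independent replicates. The same correlation was −0.202 to 0.261 in comparison 4, where the clone described as IMPDH was lower in the vector cells on 4 of 4 arrays under these signs, and the averages of its arrays of each dye order correlated at only 0.0268, so its direction rests mostly on the deposited signs. It was −0.305 to −0.0578 in comparison 1, whose arrays correlated at 0.0578 to 0.757 under the labels. The direction there is called only likely, from the signs of the deposited values, the dye marks in the file headers and the described labelling of each RNA with both dyes. Under these signs the mean of the p53 target list was above 0 on each array of comparison 1, though its median was −0.0648 on array 3. The means of the replication, mitosis and histone lists were below 0, while other lists, such as ribosomal proteins, changed sign between arrays. As these lists are also given as results of comparison 1 below, they are no separate support for its direction. In comparison 2 the correlation of arrays with opposite dye orders was −0.395 to 0.192 and no direction was settled. The mean of arrays 7 and 8 correlated with comparison 1 at 0.455 and that of arrays 5 and 6 at −0.196. The direction of comparison 1 is itself only likely, and these 2 comparisons may share an RNA. With 4 arrays from 2 RNA isolations per comparison, p-values measure the spread between arrays, which may be partly technical.

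In comparison 1, fibroblasts expressing p53 had less mRNA for H2az1, Hells and Cdk1 than p53-null fibroblasts, with the likely direction stated above. H2az1, which encodes the histone variant H2A.Z, fell by 0.87 ± 0.42 (SD, n = 4 arrays), a 1.82-fold change seen on 4 of 4 arrays (limma adjusted p = 0.0064). Hells, a chromatin remodelling helicase, fell by 0.65 ± 0.04 (adjusted p = 0.00257), and Cdk1, the kinase that drives entry into mitosis, fell by 0.59 ± 0.12 (adjusted p = 0.00739). Ephx1, the microsomal epoxide hydrolase and a member of the p53 target list, rose by 0.92 ± 0.30, or 1.89-fold, and was above background in the p53-null channel on 2 of 4 arrays (adjusted p = 0.00993). Commd3, a COMM domain protein, rose by 1.24 ± 0.26, or 2.36-fold, although it was above background in the p53-null channel on only 2 of 4 arrays (adjusted p = 0.00105).

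The remaining named genes that rose in comparison 1 were between 0.48 and 0.92. They were Etv6, an ETS family repressor, B2m, the light chain of MHC class I, the tetraspanin Cd9, the collagen-binding receptor Antxr1, the ribosomal protein gene Rpl24, the nuclear envelope gene Emd, the ferritin light chain Ftl1 and the lysosomal protease Ctsl. The brightest clone was used for each gene, and other clones differed for Etv6 (0.11 against 0.92) and Ftl1 (0.08 against 0.49). The other named falls lay between −0.71 and −0.58 and included the calcium-binding protein Sri, the spliceosome component Snrpd1, the exon junction protein Magoh, the mitochondrial chaperone Hspa9, and the signal recognition particle subunit Srp19. The transcription factor subunit Gtf2f2 was also called lower, but it was above background in each channel on only 1 array, so no size is given. Snrpd1 and Magoh were above background in the p53-expressing channel on 2 of 4 arrays. Tfpi, an inhibitor of tissue factor, was also called lower (adjusted p = 0.0163), but it was not well above background in the p53-expressing channel on any array, so no fold is given.

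By gene list, 14 of 19 histone and HMG chromatin genes were below 0 in comparison 1, and the list was lower than other genes (camera adjusted p = 1.66e-09; adjusted p = 0.0464 with an estimated correlation). H2az1 alone passed over all genes, and 9 members passed when adjusted over the list alone. Beside H2az1, Hmgn2 was at −0.45 ± 0.34 and Hmgb1 at −0.38 ± 0.07, with its other clones up to 0.06. Of 29 mitosis genes 26 were below 0 (adjusted p = 1.66e-09; adjusted p = 0.146 with an estimated correlation), with 1 member called over all genes and 3 adjusted over the list alone. Top2a, the topoisomerase of mitotic chromosomes, was at −0.61 ± 0.30 and the condensin subunit Smc2 at −0.57 ± 0.39. Of 22 DNA replication genes 16 were below 0 (adjusted p = 2.1e-06; adjusted p = 0.178 with an estimated correlation). Orc6, of the origin recognition complex, fell by 0.49 ± 0.08 (adjusted p = 0.0168) and was the 1 member called over all genes, with 4 adjusted over the list alone. Fen1, the flap endonuclease, was at −0.36 ± 0.02.

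The p53 target list was higher in p53-expressing fibroblasts, with 10 of 12 members above 0 (adjusted p = 0.00689; adjusted p = 0.295 with an estimated correlation). Ephx1 was its 1 called member, both over all genes and adjusted over the list alone. Ccng1, encoding cyclin G, was at 0.67 ± 0.44, the antiproliferative gene Btg2, above background in the p53-null channel on only 1 of 4 arrays and in the other on 2, at 0.43 ± 0.14 and Mdm2, the ubiquitin ligase that degrades p53, at 0.17 ± 0.52, on the positive side on 2 of 4 arrays. The zinc and metal response list was higher too, with 7 of 8 members above 0 (adjusted p = 0.00917; adjusted p = 0.178 with an estimated correlation). Ftl1 was its called member over all genes and adjusted over the list alone, and the metallothionein Mt1 was at 0.35 ± 0.27. Trp53 itself was at 0.19 ± 0.15 and did not pass (adjusted p = 0.81), and its clone was above background in the p53-null channel on 4 of 4 arrays.

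In all, limma called 110 of 12966 genes and unnamed clones in comparison 1, 53 higher and 57 lower, and 39 of the 110 carried a gene name. An unadjusted p under 0.05 was reached by 1001, against 648.3 expected with no change. Averaging arrays in pairs, as if each pair shared an RNA, gave 0, 16 or 703 calls depending on the pairing, and fitting its 4 arrays alone gave 0. Leaving out array 2 left 36, and the dye order printed in the labels gave 968 calls, 0 of them among the 110, and turned H2az1 to 0.36. That dye order turns the even-numbered arrays against the others, so little overlap with genes that ran one way follows from the change itself.

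In comparison 2, the 4 arrays did not run one way and limma called 0 genes, so sizes are given for each pair of arrays and no direction is stated. The metallothionein Mt1, whose promoter responds to zinc, was at 3.11 and 1.98 on arrays 7 and 8 and at −0.79 and −0.85 on arrays 5 and 6, signed as in the deposited values. Ccng1 was above 0 on arrays 7 and 8, up to 1.81, and below 0 on arrays 5 and 6, down to −0.62. Mdm2 was at 1.09 and 1.43 against −0.06 and −0.21, and H2az1 at −0.56 and −0.63 against 0.20 and 0.36. Turning all 4 arrays exchanges every sign without changing a count.

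Over the 4 arrays, Mt1 averaged 0.86 ± 2.00 (SD, n = 4 arrays; limma adjusted p = 0.695), Mt2 0.69 ± 2.55, Mdm2 0.56 ± 0.82 and Ccng1 0.59 ± 1.24. With the signs of the deposited values, 18 of 22 DNA replication genes (camera adjusted p = 0.000717; adjusted p = 0.312 with an estimated correlation) and 21 of 29 mitosis genes (adjusted p = 0.0208; adjusted p = 0.564 with an estimated correlation) lay below 0, and no member of either list passed over all genes or adjusted over the list alone. Named members were small, such as the replication protein Rpa3 at −0.20 ± 0.24, the DNA ligase Lig1 at −0.25 ± 0.31, the spindle protein Tacc3 at −0.19 ± 0.11 (another clone at 0.01) and the passenger complex gene Incenp at −0.22 ± 0.16. Both lists turned sign when arrays 7 and 8 were left out.

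The 0 calls stood beside 926 genes with an unadjusted p under 0.05, and the smallest adjusted p was 0.694. In refits chosen after the data were seen, arrays 7 and 8 alone gave 889 calls, arrays 5 and 6 alone gave 25, and turning arrays 5 and 6 gave 966. The dye order printed in the labels gave 1088.

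**Figure D1:**
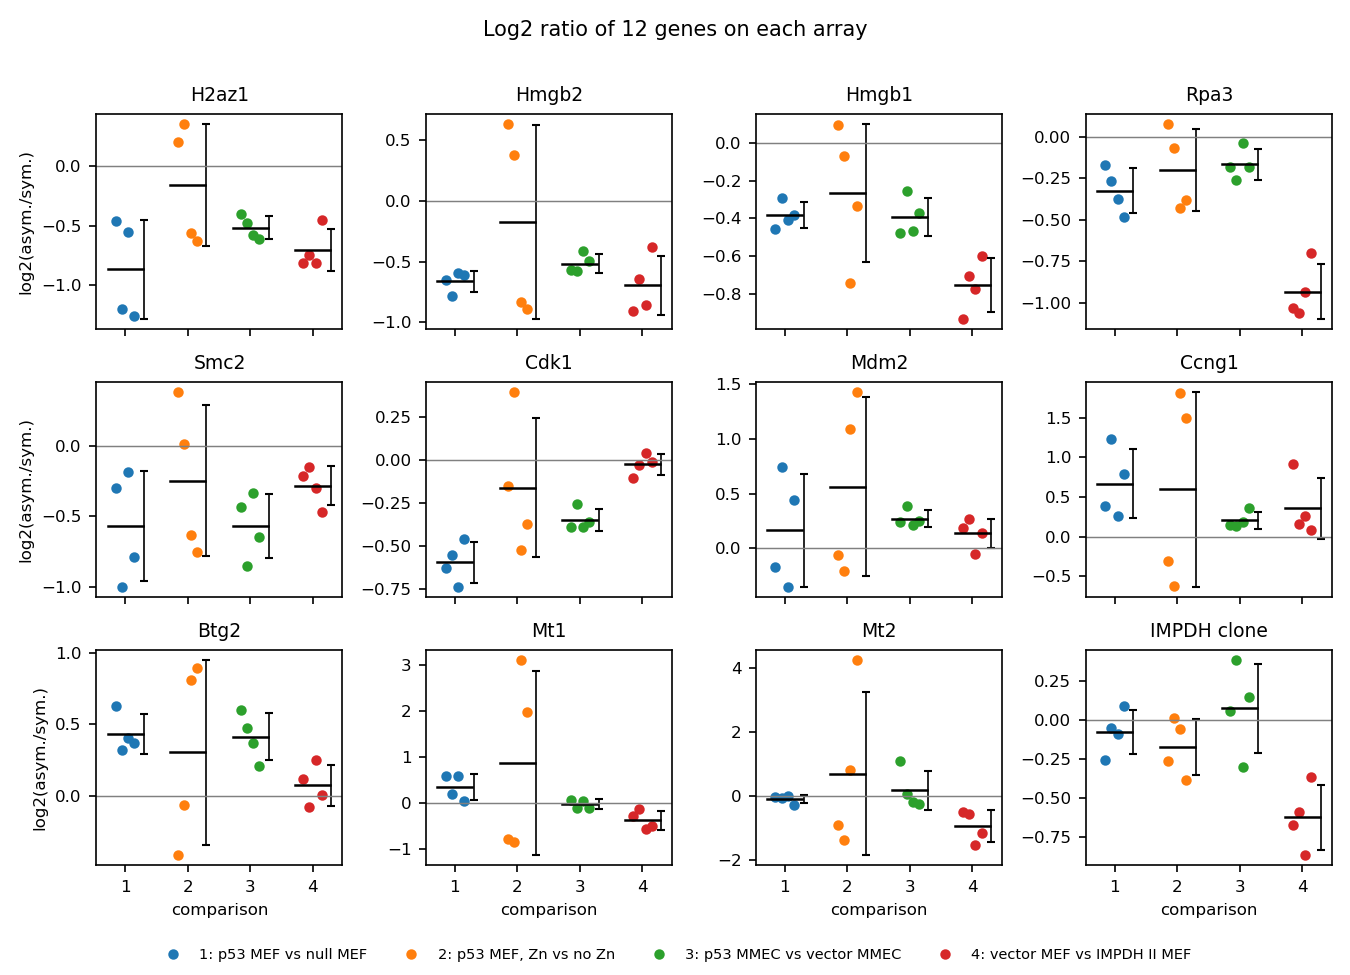
Log2 ratio of the asymmetric over the symmetric culture (vertical axes, log2 units, own scale in each panel) for 12 genes in the 4 comparisons (horizontal axes, numbered as in the legend); points are arrays in array order, the horizontal line is the mean and the bar at its right is ± 1 SD over 4 arrays. H2az1 and Hmgb2 lie below 0 on all arrays of comparisons 1, 3 and 4, while in comparison 2 arrays 5 and 6 lie above 0 and arrays 7 and 8 below it, and Mt1 spans −0.85 to 3.11 in comparison 2.

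In comparison 3, mammary epithelial cells with induced p53 (kept at 32 °C per the sample labels and 32.5 °C per the design) differed from vector cells in 56 genes and clones. Hmgn5, a nucleosome-binding protein, fell by 1.04 ± 0.17 (SD, n = 4 arrays), a 2.05-fold change on 4 of 4 arrays (limma adjusted p = 0.000156). Ccne2, the G1/S cyclin E2, fell by 0.53 ± 0.07 (adjusted p = 0.00524) and the chromatin protein gene Dek by 0.52 ± 0.14 (adjusted p = 0.0389). Anxa1, a calcium-dependent phospholipid-binding protein, rose by 0.82 ± 0.08, or 1.77-fold (adjusted p = 0.0003), and the translation elongation factor Eef1g rose by 0.79 ± 0.15 (adjusted p = 0.000863).

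The cholesterol synthesis list was lower by camera (adjusted p = 0.00617; adjusted p = 0.206 with an estimated correlation), with 4 of 7 members below 0. Its called members went both ways, over all genes and adjusted over the list alone. Sqle, the squalene epoxidase, fell by 0.49 ± 0.08, the sterol demethylation enzyme gene Msmo1 by 0.47 ± 0.14 (called higher in comparison 4, at 0.50) and the isopentenyl isomerase gene Idi1 by 0.45 ± 0.09. Scd2, which desaturates fatty acids and makes no sterol, rose by 0.60 ± 0.24 (adjusted p = 0.032). Among the other named genes that rose, between 0.51 and 0.73, were the prolactin family gene Prl7d1, the actin-sequestering Tmsb4x, the monoamine oxidase Maoa, the DNA damage binding protein Ddb1 and the spectrin Sptbn1. Azin1, an antizyme inhibitor, fell by 0.60 ± 0.05, the thioredoxin gene Txn1 by 0.46 ± 0.06, the centrin Cetn3 by 0.40 ± 0.13 and Nudt4, a diphosphoinositol phosphatase, by 0.35 ± 0.10. Other clones of Azin1 and Dek were weaker, down to −0.15 and −0.14.

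Of 22 DNA replication genes 18 were below 0 in comparison 3 (adjusted p = 1.92e-05; adjusted p = 0.206 with an estimated correlation), as were 20 of 29 mitosis genes (adjusted p = 0.0387; adjusted p = 0.589 with an estimated correlation) and 13 of 19 histone and HMG genes (adjusted p = 0.000467; adjusted p = 0.178 with an estimated correlation). No member of these 3 lists passed over all genes, and 2 of each passed adjusted over the list alone. Orc6 was at −0.36 ± 0.11, Smc2 at −0.57 ± 0.23, Cdk1 at −0.35 ± 0.06, H2az1 at −0.52 ± 0.10 and Hmgb2 at −0.52 ± 0.08, each on 4 of 4 arrays. The mitochondrial respiratory chain list was lower, with 19 of 26 members below 0 (adjusted p = 0.00232; adjusted p = 0.472 with an estimated correlation). None of its members passed over all genes and 3 passed adjusted over the list alone, with the cytochrome oxidase subunit Cox7c at −0.36 ± 0.07.

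A further 3 lists were higher. Of 16 matrix and mesenchymal genes 11 were above 0 (adjusted p = 0.00262; adjusted p = 0.206 with an estimated correlation). Timp3, a metalloproteinase inhibitor, rose by 0.51 ± 0.17 (called lower in comparison 1, at −0.39, adjusted p = 0.0239) and was the 1 member called over all genes, while 3 higher and 1 lower passed adjusted over the list alone. Of 12 glycolysis and hypoxia genes 8 were above 0 (adjusted p = 0.00262; adjusted p = 0.185 with an estimated correlation), and the phosphoglycerate mutase Pgam1, which rose by 0.56 ± 0.16, was its called member both ways. Of 52 genes in the ribosomal protein list 37 were above 0 (adjusted p = 0.00202; adjusted p = 0.589 with an estimated correlation), with 0 members called over all genes and 1 adjusted over the list alone, and Rps29 at 0.39 ± 0.10. The name pattern behind that list also took in the S6 kinase genes Rps6ka1, Rps6ka2, Rps6ka5 and Rps6kb2. The p53 targets did not pass as a list (5 of 12 above 0, median −0.01, mean 0.03, adjusted p = 0.999). Mdm2 was at 0.27 ± 0.08 and Ccng1 at 0.20 ± 0.11, each above 0 on 4 of 4 arrays and neither called. Each gene had 1 spread for all comparisons in the fit. These genes varied most on the arrays of fibroblasts with against without zinc (SD 0.82 for Mdm2 and 1.24 for Ccng1), which weakened their calls here. Their missing calls therefore do not show that Mdm2 and Ccng1 were unchanged in the mammary cells. Trp53 was at 0.27 ± 0.19.

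Limma called 56 genes and clones in comparison 3, 36 higher and 20 lower, 21 of them named, and 773 had an unadjusted p under 0.05. This comparison had the lowest median intensities. Averaging arrays in pairs gave 10, 2 or 378 calls, leaving out array 10 left 11, fitting its 4 arrays alone gave 344, and the dye order printed in the labels left 0.

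In comparison 4, the clone described as IMPDH was lower in the vector fibroblasts than in the IMPDH II fibroblasts by 1.54-fold (log2 −0.62 ± 0.21, SD, n = 4 arrays; limma adjusted p = 0.00143), on 4 of 4 arrays. The clone's description does not say which IMPDH gene it comes from, and whether it measures the transgene was not tested. Directions in comparison 4 rest mostly on the deposited signs, as stated above. Among the falls in the asymmetric vector cells, Hmgb1, a DNA-bending chromatin protein, fell by 0.75 ± 0.14 (adjusted p = 0.000207), H2az1 by 0.71 ± 0.17 (adjusted p = 0.0115) and Ptma, encoding the histone-binding prothymosin alpha, by 0.69 ± 0.16 (adjusted p = 5.77e-05). Rpa3, the smallest subunit of the single-strand DNA binding protein RPA, fell by 0.93 ± 0.16, or 1.91-fold (adjusted p = 5.13e-06). Ugp2, which makes UDP-glucose, rose by 0.81 ± 0.15, or 1.75-fold, and Ccnd2, the G1 cyclin D2, by 0.76 ± 0.32 (adjusted p = 0.0126).

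The deepest named falls in comparison 4 were in Pfdn1, a prefoldin subunit, by 1.19 ± 0.22 (2.28-fold, adjusted p = 9.32e-06), and in the splicing protein gene Zranb2, by 1.05 ± 0.14 (2.06-fold). Fubp1, a single-strand DNA binding regulator, Rabggtb, a Rab prenylation subunit, Cst3, the protease inhibitor cystatin C, the growth arrest gene Gas1, the dynactin subunit Dctn4, the chemokine Cxcl1 and the sodium pump subunit Atp1b1 fell by between 0.77 and 0.89. Weaker clones of Fubp1 and Hmgb1 reached −0.37 and 0.06. Among the other rises, the acid ceramidase Asah1 rose by 0.70 ± 0.21, the proton pump subunits Atp6v1g1 by 0.71 ± 0.28 and Atp6v0c by 0.55 ± 0.20, clathrin heavy chain Cltc by 0.57 ± 0.31 and Vapa, a membrane contact protein, by 0.55 ± 0.06. The HMG gene Hmga1 rose by 0.66 ± 0.44, the kinase Fyn by 0.56 ± 0.18 and the Ras suppressor Rsu1 by 0.56 ± 0.15.

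The histone and HMG list was lower in comparison 4, with 15 of 19 members below 0 (camera adjusted p = 2.31e-05; adjusted p = 0.155 with an estimated correlation). Over all genes 7 members were called lower and Hmga1 higher, and adjusted over the list alone 9 were lower and 2 higher. The mitosis list was lower as well, with 21 of 29 members below 0 (adjusted p = 0.00917; adjusted p = 0.472 with an estimated correlation). The centromeric histone Cenpa fell by 0.59 ± 0.22 and was the 1 member called over all genes, against 2 adjusted over the list alone. The DNA replication list did not pass (13 of 22 below 0, adjusted p = 0.29), although 2 of its members, Rpa3 among them, were called lower over all genes and 2 adjusted over the list alone. Of 26 respiratory chain genes 16 were below 0 (adjusted p = 0.0172; adjusted p = 0.589 with an estimated correlation). Cox7c fell by 0.61 ± 0.14, Cox6b1 by 0.63 ± 0.28, Ndufs6 by 0.45 ± 0.31 and Ndufb5 by 0.33 ± 0.22, the 4 members called over all genes, while 9 lower and 2 higher passed adjusted over the list alone. Of 16 matrix and mesenchymal genes 11 were above 0 (adjusted p = 0.012; adjusted p = 0.295 with an estimated correlation). Tnc, encoding tenascin C, rose by 0.55 ± 0.14 and the fibulin Fbln2 by 0.41 ± 0.15, the 2 members called over all genes, with 4 higher and 1 lower adjusted over the list alone. The p53 targets were not called (9 of 12 above 0, adjusted p = 0.526), with Ccng1 at 0.35 ± 0.38 and Mdm2 at 0.14 ± 0.13. Trp53 was at 0.10 ± 0.16.

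Limma called 358 genes and clones in comparison 4, 137 higher and 221 lower, 123 of them named, and 1529 had an unadjusted p under 0.05. Averaging arrays in pairs gave 149, 67 or 1193 calls and leaving out array 13 left 130, while the dye order printed in the labels gave 491, 0 of them among the 358.

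In the mean of the 4 comparisons the histone and HMG list was lower, with 16 of 19 genes below 0 (camera adjusted p = 6.21e-09; adjusted p = 0.0464 with an estimated correlation). H2az1 fell in the mean by 0.56 ± 0.41 (SD, n = 16 arrays), below 0 on 14 of 16 arrays (limma adjusted p = 0.000346), with its 4 clones between −0.57 and −0.54. Hmgb2, a chromatin protein of dividing cells, fell by 0.51 ± 0.43 (14 of 16 arrays, adjusted p = 0.00273) and Hmgb1 by 0.45 ± 0.26 (15 of 16 arrays, adjusted p = 7.6e-05), although another of its 4 clones was at 0.00711. Rpa3 fell by 0.41 ± 0.35 (15 of 16 arrays, adjusted p = 7.6e-05), Smc2 by 0.41 ± 0.36 and Cdk1 by 0.28 ± 0.29, both on 14 of 16 arrays. Btg2 was the p53 target called in the mean, where it rose by 0.30 ± 0.34 (13 of 16 arrays, adjusted p = 0.03). With comparison 2 turned, Smc2, Cdk1 and Btg2 no longer passed.

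With the deposited signs of comparison 2, 57 named genes called higher in the mean and 66 called lower had one sign in all 4 comparisons. They were ranked by the smallest, in size, of their 4 ratios, so that genes with a larger mean can be missing, and the 10 highest and 10 lowest are named. With comparison 2 turned, 4 and 9 other named genes met this condition, and of the 20 named Etv6, Gpr137b, Hmgb1, Shcbp1, Ivns1abp, Hmgb2, Rpa3 and H2az1 still passed in the mean. Of the falls not given above these were the cell division genes Shcbp1 (−0.35), Ttk (−0.28) and Melk (−0.22), the influenza NS1 binding protein gene Ivns1abp (−0.32) and the prefoldin subunit Vbp1, which lay below 0 on 16 of 16 arrays (−0.23 ± 0.13). The rises were the potassium channel Kcnn4 (0.57), the glutathione transferase Gsta4 (0.50), Etv6 (0.46), the lysosomal membrane protein gene Gpr137b (0.46), Glipr1 (0.27), the glycolytic gene Gapdh (0.27), the lysosomal peptidase Tpp1 (0.26), Midn (0.25), Tulp4 (0.25) and the poly(A) binding protein gene Pabpc1 (0.24). Other clones of Etv6, Gpr137b, Gapdh and Tulp4 lay near −0.03, −0.01, −0.02 and 0.01, and another clone of Ivns1abp at −0.05.

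Of the histone and HMG list, 6 members were called lower and 1 higher in the mean over all genes, and 9 lower and 2 higher adjusted over the list alone. Of 29 mitosis genes 26 were below 0 (adjusted p = 5.16e-08; adjusted p = 0.155 with an estimated correlation), 4 called lower over all genes and 10 adjusted over the list alone. Of 22 replication genes 17 were below 0 (adjusted p = 1.02e-07; adjusted p = 0.155 with an estimated correlation), again 4 over all genes and 10 adjusted over the list alone. The matrix and mesenchymal list was higher (11 of 16 above 0, adjusted p = 0.0126; adjusted p = 0.295 with an estimated correlation), with Fbln2 at 0.20 ± 0.22 called over all genes (not with comparison 2 turned) and 6 members adjusted over the list alone. The p53 targets were higher by camera (9 of 12 above 0, adjusted p = 0.0494; adjusted p = 0.472 with an estimated correlation), but not with comparison 2 turned, with 1 member over all genes and 4 adjusted over the list alone.

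**Figure D2:**
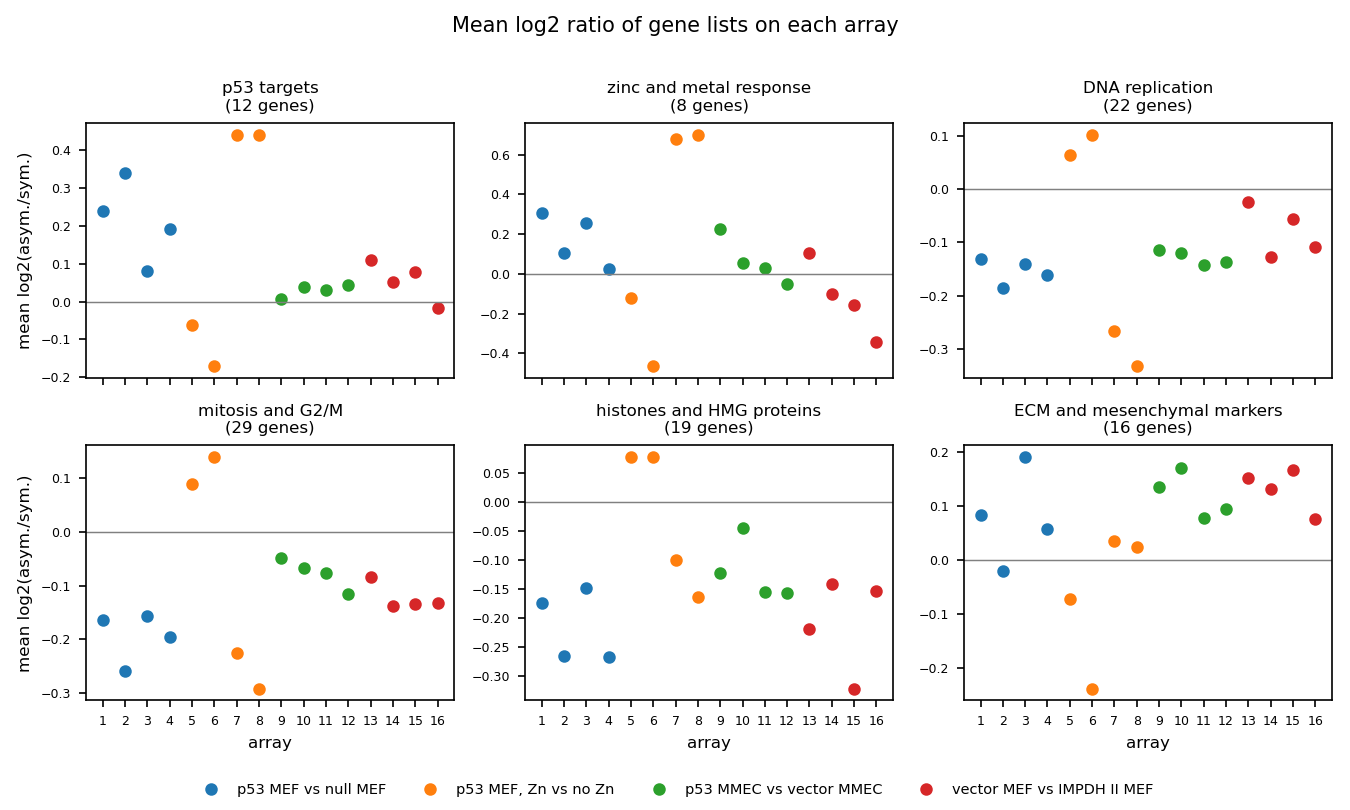
Mean log2 ratio of the asymmetric over the symmetric culture (vertical axes, log2 units, own scale in each panel) of 6 gene lists on each of the 16 arrays (horizontal axes); each point is the mean over the genes of the list on that array, coloured by comparison, signed as in the deposited values. The replication, mitosis and chromatin lists lie below 0 on every array except arrays 5 and 6, and the p53 target and metal response lists are highest on arrays 7 and 8.

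A set of 8 lists passed in none of the 4 comparisons or their mean. Their lowest adjusted p was 0.117 for actin and contractile genes, 0.137 for stem cell-associated genes, 0.177 for epithelial markers, 0.202 for heat shock proteins and chaperones, 0.272 for purine and guanine synthesis, 0.308 for the proteasome, 0.339 for ribosome biogenesis and 0.449 for hematopoietic and macrophage markers. Of the 90 list tests 24 passed, against a median of 9 when the signs of arrays were drawn at random, and 2 passed with an estimated correlation, those of the histone and HMG list in comparison 1 and in the mean.

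The mean of the 4 comparisons called 422 genes and clones, 209 higher and 213 lower, 159 of them named. Limma called 0 genes the same way in comparisons 1, 3 and 4 (0.00305 expected), where 69 had an unadjusted p under 0.05 and one sign in each (1.73 expected). The fit shares its spread over all arrays, and the opposed arrays of comparison 2 widen it, so this 0 depends on them. With arrays 5 and 6 left out, chosen after the data were seen, 9 genes and clones were called the same way in all 4. H2az1, Hmgb1 and Hmgb2 were among them. As comparison 2 had 0 calls in the fit of all arrays, the count over all 4 there could only be 0. Over all 4, 8 had an unadjusted p under 0.05 and one sign in each, against 0.0615 expected for independent lists and 0 with comparison 2 turned, and when arrays 5 and 6 were turned, a refit chosen after the data were seen, 6 were called, among them H2az1 and Hmgb2. In pairs, comparisons 1 and 3 shared 7 higher and 2 lower genes (0.147 and 0.0879 expected), comparisons 1 and 4 shared 6 and 16 (0.56 and 0.972 expected) and comparisons 3 and 4 shared 3 and 3 (0.38 and 0.341 expected), while 1, 4 and 3 genes were called in opposite directions. The expected counts hold for independent lists. Each gene has 1 spread for all comparisons in the fit, so its calls in different comparisons are not independent and the expected counts may be too low. The cells in zinc of comparisons 1 and 2 are the same line and may be the same RNA. Averaging arrays in pairs gave 58, 59 or 1539 calls in the mean, leaving out array 9 left 249, turning comparison 2, whose direction is not settled, left 170 of which 139 were among the 422, and the dye order printed in the labels gave 1944 calls, 0 of them among the 422, 1 passing list test and H2az1 at 0.06.

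The 3 comparisons with a p53 difference were then set against comparison 4. In the difference between their mean and comparison 4, 138 genes and clones passed, 106 with a higher ratio in the p53 comparisons and 32 with a lower one, 44 of them named. B2m was at 0.46 in the mean of the p53 comparisons and −0.43 in comparison 4, a difference of 0.89 (limma adjusted p = 0.00546). Cxcl1 (0.16 against −0.80, adjusted p = 0.000117), Cst3 (0.09 against −0.87) and Cox6b1 (0.16 against −0.63) differed in the same sense. Msmo1 was at −0.12 against 0.50 and Asah1 at 0.09 against 0.70, the opposite sense. Rpa3 was lower in both, at −0.23 and −0.93, and differed in size by 0.70 (adjusted p = 0.00122). The mean holds comparison 2, whose direction is not settled: turning it again gave 138 calls, 107 of them among those above, with each of the 7 genes named here passing and the p53 means of Cst3 and Cox6b1 changing sign, to −0.0815 and −0.0103. Averaging arrays in pairs gave 32, 12 or 664 calls, leaving out array 13 left 60, and the dye order printed in the labels gave 34, 0 of them among the 138.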

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

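The tests of the zinc comparison's arrays, of single arrays and comparisons, and of the dye order, and the sign splits within each comparison, were chosen only after the results were seen.

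An array stood apart from the other 3 in 2 of 219 groups tested, where chance would give about 1 in 20. Cd9 was at 0.49 on array 1 of comparison 1, against 0.60 to 0.61 on the others, and the mitosis list was at −0.0834 on array 13 of comparison 4, against −0.138 to −0.133.

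The p53 comparisons and the IMPDH comparison differed for 44 named genes by limma's test of the difference (p53 mean minus IMPDH comparison, log2), and the 18 of them that were also named for another comparison are given here. The difference was 0.89 for B2m, 0.44 for Ccne2, 1.02 for Pfdn1, 0.87 for Zranb2, 0.70 for Rpa3, 0.83 for Fubp1, 0.80 for Rabggtb, 0.96 for Cst3, 0.89 for Dctn4, 0.96 for Cxcl1, 0.73 for Atp1b1, 0.57 for the IMPDH clone, 0.53 for Ptma, 0.49 for Cox7c and 0.80 for Cox6b1. It was −0.62 for Msmo1, −0.61 for Asah1 and −0.58 for Tnc. Most of these genes were named because they were called in comparison 4. With comparison 2 turned, Tnc no longer passed (−0.479, adjusted p = 0.0976) and the other 17 did. Of 100 splits of the 16 arrays into 12 and 4, 2 gave as many calls as the 138 of this contrast, the real one included, and the highest other gave 154. The other splits mix arrays of different comparisons in the groups, which widens the spread of the fit whether or not comparison 4 differs. This share therefore cannot exclude chance for the contrast.

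In comparison 2, arrays 5 and 6 ran opposite to arrays 7 and 8, with r = −0.350 over genes. Gene-specific dye bias cancels within each pair and does not give a negative correlation between pairs, so that value argues against it. Zinc having no effect on arrays 5 and 6 is argued against by Mt1, at −0.823 there with an SE of 0.133. An exchange of channels with nothing else different would put the slope near −1 if both pairs were equally noisy, and it was −0.608 with a bootstrap SE of 0.0174. That SE resamples genes and does not measure noise between arrays. Arrays 5 and 6 correlated with each other at −0.0667 and arrays 7 and 8 at 0.192, so the slope cannot decide the question. A candidate explanation that stays open is that 2 of the 4 arrays were not turned as the deposited values state, with or without a further difference between the RNAs. The r of −0.350 prompted this explanation and is no test of it. Mt1, whose promoter responds to zinc, was below 0 on arrays 5 and 6, which goes with those being the 2 arrays. It is 1 gene and does not settle the question. Apart from zinc having no effect no biological explanation was tested.

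Replication, mitosis and chromatin genes lay lower in the mean of the 4 comparisons, with 59 of 70 below 0 and a median of −0.0917. Spot brightness is argued against by 10000 random lists of matched brightness, of which none was as low (lowest −0.0317), a share printed as 0.01%, the smallest they can give. A single array, or the zinc comparison, is argued against by the highest median after leaving each of these out, −0.0849. Dye order is argued against by the medians in both orders in comparisons 1, 3 and 4, −0.110 and −0.147. The pattern may reflect slower cycling of the asymmetric cultures, a hypothesis that no value here measures, and it rests on the signs of the deposited values, since the labels' orientation puts the mitosis list at 0.0370.

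Of the 8 sign splits of each comparison's arrays, too few for a share under 0.05, 2 gave as many calls as comparison 1 (110, highest other 699), 8 as many as comparison 2 (0, highest other 966), 1 as comparison 3 (56, highest other 0) and 1 as comparison 4 (358, highest other 107). The 699 calls came from turning arrays 2 and 4, which is the labels' orientation. For the mean, 2 of 100 drawn sign splits of the 16 arrays gave as many as 422, and the highest other gave 1194 by turning arrays 2, 4, 7, 8, 9, 10, 12, 14 and 16. That split holds the turns with the highest other counts in comparisons 1, 2 and 4, those of arrays 2 and 4, 7 and 8, and 14 and 16. In comparisons 1 and 4 these are the labels' orientation, and in comparison 2 they make the arrays run one way. The labels' orientation of all arrays gave 1944 calls in the mean and turning arrays 5 and 6 gave 1346, both above 422. For the list shifts 2 of 100 splits gave as many as 24, the highest other gave 25 and the median of the other 99 was 9. For the mean and for the lists chance was excluded at a share under 0.05 only for arrays taken as independent, which arrays that share an RNA isolation are not, and averaging arrays in pairs gave 58, 59 or 1539 calls in the mean.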

How the results depend on the processing

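The refits with the first exposure and those that turn or leave out arrays 5 to 8 were chosen only after the results were seen. Dropping the dim-probe filter, requiring both channels on all arrays, keeping the maker's marks, 1 dye coefficient and averaging clones kept each count of called genes and lists within 1.5 times. In the order comparison 1, 2, 3, 4, mean and p53 minus IMPDH, the reported counts were 110, 0, 56, 358, 422 and 138, and those below are only the ones that moved by more; the cause was not tested.

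Without background subtraction comparisons 1, 3 and 4 had 741, 16 and 160 calls and the difference 61. The scanner's ratio gave 28, 1, 28, 148, 201 and 57. Median centring gave 9, 5 and 86 in comparisons 1, 3 and 4, 113 for the mean and 25 for the difference, split 22 higher to 64 lower in comparison 4 (137 to 221 as reported) and 24 to 1 in the difference (106 to 32). Scaling between arrays gave 255 in comparison 1, 686 in comparison 3 and 691 for the mean. The deposited table gave 34 in comparison 1 and 72 for the difference. Array weights gave 288, 773 and 688 in comparisons 1, 3 and 4 and 209 for the difference. Separate fits of 4 arrays gave 0, 344 and 218 in comparisons 1, 3 and 4, with 3 degrees of freedom each and no value for the mean or difference. A 1.2-fold minimum left 4, 3 and 37 in comparisons 1, 3 and 4, 0 for the mean and 16 for the difference. The first exposure gave 173 in comparison 1 and 32 in comparison 3. With an estimated correlation 2 lists passed in place of 24.

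No pairing of arrays by RNA was possible, because no label says which arrays share an RNA isolation. Each array itself holds a pair of cultures. In the pairings below, the arrays numbered 1 and 3 have the same dye order under the deposited signs, so that pairing averages no dye swap. Averaging arrays that might share RNA gave, for the arrays numbered 1 and 2 within each comparison, 0, 10 and 149 calls in comparisons 1, 3 and 4, 58 for the mean and 32 for the difference; for 1 and 3, 16, 2, 67, 59 and 12; and for 1 and 4, 703, 133, 378, 1193, 1539 and 664 in all 6, with 2 genes shared by all comparisons.

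Turning comparison 2 gave 170 for the mean and ended the call of 18 named-gene results and 1 list test, that of p53 targets in the mean. Turning arrays 5 and 6 gave 234, 966 and 113 in comparisons 1 to 3, 1346 for the mean and 6 genes shared by all; with a dye coefficient 319, 1441, 159, 680, 1799 and 262, and 10 shared; averaged in pairs 229 and 1383 in comparisons 1 and 2, 583 in comparison 4, 1617 for the mean and 7 shared. Without arrays 5 and 6 the counts were 287, 889, 123, 580, 1543 and 228, with 9 shared. Without arrays 7 and 8 they were 268, 25, 121, 547, 229 and 249. Without comparison 2 they were 303, 130 and 625 in comparisons 1, 3 and 4, with no value for the mean or difference. Leaving out each array gave 36 (array 2) to 158 in comparison 1, 0 to 1 in comparison 2, 11 (array 10) to 75 in comparison 3, 130 (array 13) to 413 in comparison 4, 249 (array 9) to 632 for the mean, 60 (array 13) to 164 for the difference, 19 (array 15) to 26 for lists and 0 to 0 shared by all, a count that comparison 2 holds near 0.

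The labels' orientation gave 968, 1088 and 0 in comparisons 1 to 3, 1944 for the mean, 34 for the difference and 1 list. It reversed in comparison 1 Commd3 (−0.17), Cd9 (−0.0248), Antxr1 (−0.31), Rpl24 (−0.16), Emd (−0.26), H2az1 (0.36), Sri (0.0316), Snrpd1 (0.21), Hspa9 (0.0198) and Srp19 (0.22); in comparison 3 Eef1g (−0.11), Prl7d1 (−0.0583), Tmsb4x (−0.0921), Pgam1 (−0.13), Sptbn1 (−0.041), Timp3 (−0.11), Msmo1 (0.0623) and Nudt4 (0.0329). In comparison 4 it reversed Ugp2 (−0.0661), Ccnd2 (−0.0328), Atp6v1g1 (−0.16), Asah1 (−0.0117), Hmga1 (−0.0363), Vapa (−0.0473), Atp6v0c (−0.0175), Tnc (−0.0991) and Fbln2 (−0.041), and in the mean Kcnn4 (−0.00281), Gsta4 (−0.14), Smc2 (0.17), Rpa3 (0.0195), H2az1 (0.0635), Cenpa (0.037) and Fbln2 (−0.0747). For lists that passed as reported it reversed the direction given by camera, with none passing, for (medians under it) p53 targets (−0.0842), replication (0.0410), mitosis (0.0478) and histones (0.0650) in comparison 1, mitosis (0.010), ribosomal proteins (−0.000308), respiratory chain (0.00453), glycolysis (−0.0316) and matrix (0.00236, a median still above 0) in comparison 3, mitosis (−0.00555, still below 0) in comparison 4, and p53 targets (−0.00721), replication (0.0219) and mitosis (0.0370) in the mean. Without a reversal it ended the call of a further 66 named-gene results and 11 list tests, and none of its calls was among those reported for any comparison, the mean or the difference. As it sets the even-numbered arrays against the others, ratios that ran one way cancel under it, so the missing overlap and values near 0 follow largely from the change itself.

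Other reversals were Trp53 in comparison 2 with arrays 5 and 6 turned and a dye coefficient (0.27), Mt1 without arrays 7 and 8 (−0.82 in comparison 2, −0.22 in the mean), Dut in the mean without background subtraction (0.0800), and the replication and mitosis lists in comparison 2, at 0.12 and 0.0655 when it was turned and 0.0660 and 0.12 without arrays 7 and 8. A change of sign counted only where a value passed the test. Turning every array swaps rises and falls and changes no count. The slide or scan block was not run, as no batch was found in the files used here. Signal over background limits single ratios in comparison 1, where 73.9% to 84.5% of clones were above background in both dyes and where Commd3, Ephx1, Btg2 and Tfpi were above it in the p53-null channel on 2 or fewer of 4 arrays.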

Other observations

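In comparison 4, members of lists that did not pass as a whole were also called, here chosen after their values were seen. Of the ribosomal protein genes, Rpl13a fell by 0.63 (limma adjusted p = 0.00193), Rpl28 by 0.42, Rpl18 by 0.41, Rps21 by 0.37 and Rplp1 by 0.34, while Rpl36 rose by 0.55 (adjusted p = 0.0078). The lactate dehydrogenase gene Ldha fell by 0.66 (adjusted p = 0.000207), the proteasome subunits Psma5 by 0.40 and Psma2 by 0.34, and Aprt, which salvages adenine, rose by 0.40 (adjusted p = 0.0292).

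Lists with fewer than 5 measured members were not tested as sets. Of the interferon and antigen presentation genes, B2m was called in comparison 1 and was at 0.50 in comparison 3 and −0.43 in comparison 4, neither called, while Stat2 and Irf9 were called in none. None of the adipocyte and muscle markers Ckm, Lpl and Plin1 was called. Of the study's candidates only H2az1 was measured by a named clone. The metallothionein Mt2 was at −0.95 ± 0.49 in comparison 4, where both cultures were in zinc, below 0 on 4 of 4 arrays and not called (limma adjusted p = 0.568). Its spread in the fit also took in the arrays of fibroblasts with against without zinc (SD 2.55), so the missing call does not show that Mt2 was unchanged.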
